A study of Rattus norvegicus with 12 samples.

How the data were processed

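Retinal RNA from 12 rat libraries in 4 groups of 3 was analysed. Per the labels' protocols, RNA was isolated from dissected retinas and sequenced as single-end reads on an Illumina instrument. The protocol text speaks of miRNA libraries, while the deposited table lists Ensembl genes; its values are treated here as gene expression. The submitters' processing notes name FastQC, TopHat, Cufflinks and Cuffdiff and the genome build rn6 without roles or versions. The counting tool and the annotation release are not given in the sources used here.

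The authors deposited 1 table of TPM values with 32883 Ensembl gene identifiers and 12 columns. Each column was assigned to a sample through the lines above the table, which pair the sample titles with the column names, and 0 columns were left unassigned. The records of OIR scrambled replicate 3 and OIR mimic replicate 1 lack the tags for disease and transfection; their groups come from the titles. The column names carry a number and a letter. The letter L stands in each mimic column and the letter R in each scrambled column, so whatever the letter stands for cannot be separated from the injection. Sham scrambled replicate 1 and sham mimic replicate 1 carry the same number, whose meaning is not given in the sources used here. The numbers run from 286 to 293 in the sham columns and from 299 to 310 in the OIR columns. Whatever they order therefore cannot be separated from OIR.

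The annotation table supplied with the reference holds 47357 genes and 0 Ensembl identifiers, so 0 identifiers were matched to a symbol. The files do not pair identifiers with names. The planned tests of fixed gene lists, of miR-143 seed sites, of genes chosen by symbol, and the rescaling without mitochondrial, haemoglobin, crystallin and small RNA genes were therefore not run.

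The TPM values were whole multiples of the value of 1 read per gene and library, which allowed the reads and the gene lengths to be recovered for 22309 of the 22310 rows with a value above 0, with a tolerance of 0.02 for a whole number. TPM recomputed from them differed by a relative error of at most 9.2e-07. The recovery was tested on simulated data, in which 100.0% of the counts of 2814 genes came out exact. These were the simulated genes above a set minimum of reads that gave whole counts, and genes with fewer reads were not scored. The smallest whole numbers that fit were taken. Reads and length of a gene could therefore both be a multiple of those given, above all where reads are few. Libraries had 10537600 to 13175005 reads on genes. The recovered reads served for depth, for counting precision and for 1 added alternative, and the tests rest on TPM as deposited.

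Genes with a TPM of at least 1 in at least 3 of the 12 libraries were kept, 15916 in all. Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, 8 residual degrees of freedom, and eBayes with trend and robust options. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes on this scale understate the change of low genes. The comparisons were OIR against sham with scrambled RNA, with the mimic and averaged over both, mimic against scrambled RNA in OIR and in sham, and the interaction. The fit was tested on simulated data with 200 changed genes in each of 5 draws. For OIR against sham with scrambled RNA, 66.4% of 2-fold and 48.8% of 1.5-fold changes were called and 6.04% of the calls were false. For the mimic in sham the shares were 66.8% and 44.2%. Genes varied independently in these simulations, so the shares need not hold for libraries with a common structure.

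The rule for genes given by identifier was fixed before the data were examined, except that its condition on gene symbols could not be used. From OIR against sham with scrambled RNA it took the 10 genes with the largest log2 fold change in each direction. These had to be past the threshold, with groups that did not overlap and a mean of at least 5 TPM in the higher group. Only the first 2 in each direction are given here, a number that the rule did not set. The rule also covered the mimic in OIR and in sham and the interaction, where it would have added genes that missed the threshold. No genes are given from these. For the other comparisons it set only counts, gene lists and genes chosen by symbol. In OIR against sham with scrambled RNA, 935 higher and 570 lower genes met these conditions. By chance 10% of genes have groups of 3 that do not overlap. That is not the chance share of genes that also pass the threshold and the level.

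Standard errors of correlations across genes come from leaving out each library within its group (jackknife). Chance values for comparisons that share libraries come from 100 simulated sets without effects. Exact permutation tests enumerate each division of the libraries. Other settings fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalisation, eBayes without trend and robust options, arrayWeights, fits on only the 2 groups compared, the replicate number as a block, leaving out each library, and leaving out both libraries that lack tags. Chosen after seeing the data were limma voom on the recovered reads, the state of a block of on/off genes as a covariate, leaving out both libraries with the shared number, and scaling each library to the total of the genes outside the 10 most abundant of the sham libraries. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.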

Results

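RNA-seq profiles of 12 rat retinas were compared in a design of 4 groups with 3 libraries each. The animals were wild-type Sprague Dawley rats at postnatal day 18. In 2 of the groups the pups had oxygen-induced retinopathy (OIR), a rodent model in which changes in oxygen during the growth of the retinal vessels first stop that growth and later provoke abnormal new vessels. The other two groups were sham controls. Within OIR and within sham, 1 group had received a mimic of the microRNA miR-143, a synthetic RNA that acts as the mature microRNA, and 1 group a scrambled RNA as its control. The title of the series gives its subject as the role of miR-143 in ischaemic retinopathy. The comparisons below ask what OIR changed in the retinal transcriptome, what the mimic changed with and without OIR, and whether the effect of the mimic differed between them.

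Values were TPM, read counts divided by gene length and scaled to one total in each library, for 32883 Ensembl genes, of which 22310 had a value above 0 in at least 1 library. Between 10537600 and 13175005 reads per library lay on genes, as recovered from the TPM values. In a gene of 2000 bases, 1 read corresponds to 0.0781 to 0.0987 TPM depending on the library, so genes near 1 TPM rest on few reads. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries. Replicates differed by more than counting error in each of the 12 pairs within groups, with a chi-square per degree of freedom of 4.54 to 22.1. The files do not pair the gene identifiers with names, so genes are described by abundance and direction, and 4 are given by identifier.

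On the first principal component of log2(TPM + 1), which held 34.4% of the variance, the 6 OIR libraries lay apart from the 6 sham libraries. The sham libraries lay between -28.2 and -23.7, and the OIR libraries between 15.6 and 37.6. The second component held 14.1% and did not separate mimic from scrambled RNA within either condition. OIR scrambled replicate 3 had the largest root-mean-square distance from its group mean, 0.297 on the log2 scale, against 0.221 for the closest library.

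**Figure D1:**
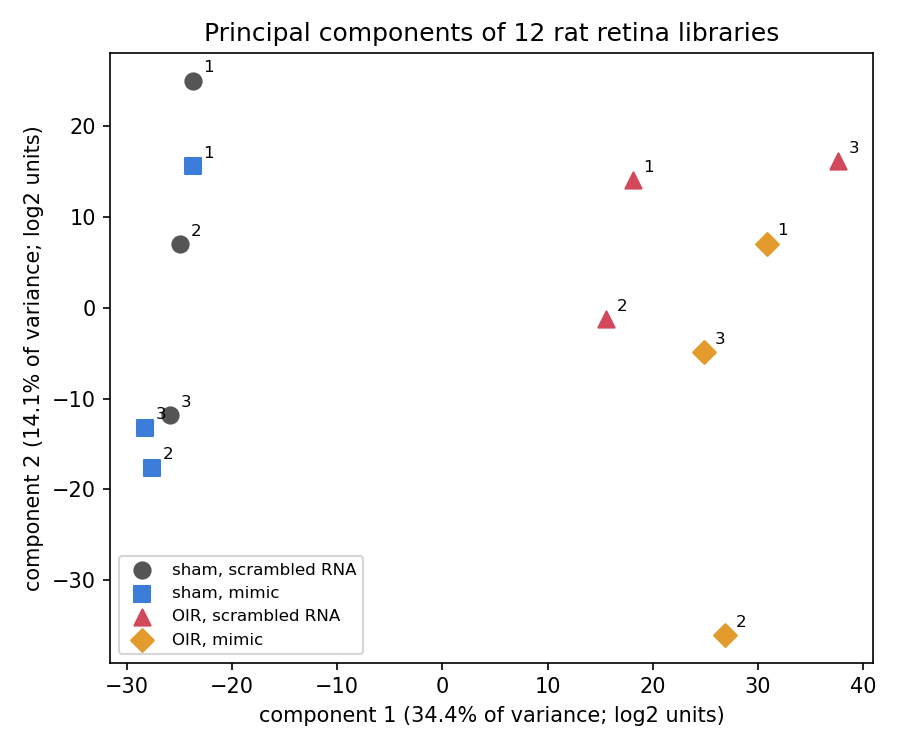
Position of the 12 libraries on the first and second principal components of log2(TPM + 1), in log2 units, with 1 point per library and the replicate number beside it. Sham libraries lie at or below -23.7 on the first component and OIR libraries at or above 15.6.

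In retinas given scrambled RNA, 1704 of 15916 tested genes differed between OIR and sham (limma, Benjamini-Hochberg adjusted p below 0.05). Of the 1704 genes, 1081 were higher and 623 lower in OIR than in sham. Sham and OIR columns carry separate runs of numbers, so number and condition go together. The median absolute log2 fold change of these genes was 0.60. More than a 2-fold change on the log2(TPM + 1) scale was estimated for 357 of them, of which 48 were lower (223 without OIR scrambled replicate 3). The gene ENSRNOG00000002946 rose from 1.54 ± 0.777 TPM in sham to 53.2 ± 26.1 TPM in OIR (SD, n = 3), a log2 fold change of 4.36 (SE 0.49) with a limma adjusted p of 0.000909. The gene ENSRNOG00000014350 rose from 3.45 ± 1.08 to 65.7 ± 33.8 TPM (SD, n = 3), a log2 fold change of 3.83 (SE 0.67) with a limma adjusted p of 0.00683. The gene ENSRNOG00000005826 fell from 46.4 ± 4.46 to 0.522 ± 0.165 TPM (SD, n = 3), a log2 fold change of -4.96 (SE 1.02) with a limma adjusted p of 0.014. Its OIR value rests on 1 or 2 reads per library, and in the sham mimic group 1 library stood at 0.566 TPM while another reached 51.5 TPM. This gene is 1 of 19 with an on/off pattern between libraries. The call of this gene was lost without the 2 libraries lacking condition tags (log2 fold change -5.01, limma adjusted p 0.0531). It was also lost with voom on recovered reads (log2 fold change -6.11, limma adjusted p 0.163). The gene ENSRNOG00000060706 was listed at 0 in each of the 3 OIR libraries and at 2.40 to 12.6 TPM in sham, with a limma adjusted p of 0.0217. That difference rests on 10 reads, as recovered, in the 3 sham libraries together over a recovered length of 82 bases. The call was lost in 5 of 26 alternative settings.

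The excess of higher over lower genes depended on the scaling. With TPM as deposited, 63.4% of the called genes were higher in OIR. After median-ratio scaling the share was 49.9% of 1958 genes, and after quantile normalisation 44.8% of 2133 genes. Both bring the median fold change close to 0, so these shares do not show where the excess comes from. Beyond 2-fold, 86.6% of the called genes were higher, and 84.2% after median-ratio scaling. On the log2(TPM + 1) scale a gene at or below 1 TPM in each sham library cannot fall by more than 2-fold. The number of called genes depended on single libraries. It was 847 genes without OIR scrambled replicate 3, 914 without sham scrambled replicate 1, 805 without sham scrambled replicate 2 and 1088 without sham scrambled replicate 3.

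Among genes with a mean below 10 TPM, 362 were higher and 153 lower in OIR with scrambled RNA. Between 10 and 100 TPM, 564 were higher and 332 lower. Between 100 and 1000 TPM the numbers were 146 and 128, and above 1000 TPM they were 9 and 10. The share of tested genes that were called grew with abundance, from 9.17% in the lowest class to 23.2% in the highest.

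In retinas given the mimic, 3108 genes differed between OIR and sham, 1553 of them higher and 1555 lower in OIR (limma, adjusted p below 0.05). The even division depended on scaling and on single libraries. The share of higher genes was 43.3% of 3323 genes after median-ratio scaling and 43.2% of 3400 after quantile normalisation. It was 39.4% without OIR mimic replicate 1 and 56.4% without OIR mimic replicate 2. The count was 2041 without sham mimic replicate 3. ENSRNOG00000002946 and ENSRNOG00000014350 were again higher in OIR, with log2 fold changes of 3.12 (SE 0.49) and 2.26 (SE 0.67) and limma adjusted p of 0.00214 and 0.039. OIR mimic levels of the latter ranged from 4.60 to 53.1 TPM. For ENSRNOG00000005826 the log2 fold change was -3.07 (SE 1.02) with a limma adjusted p of 0.0596, and for ENSRNOG00000060706 it was -0.72 (SE 0.66) with a limma adjusted p of 0.495.

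The OIR effects of the scrambled and the mimic groups come from libraries that are not shared, and they resembled each other. Across the 15916 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.702 (jackknife SE over libraries 0.0433) and a Spearman rho of 0.70. Of the genes called higher with scrambled RNA, 858 were also called higher with the mimic, where independent lists of these sizes would share 105.5. Of those called lower, 524 were shared, against 60.9 for independent lists. Both lists come from the same fit with a common spread per gene, and the share called grew with abundance in both. Lists with unrelated effects could therefore share more than independent ones. A single gene was called in opposite directions.

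**Figure D2:**
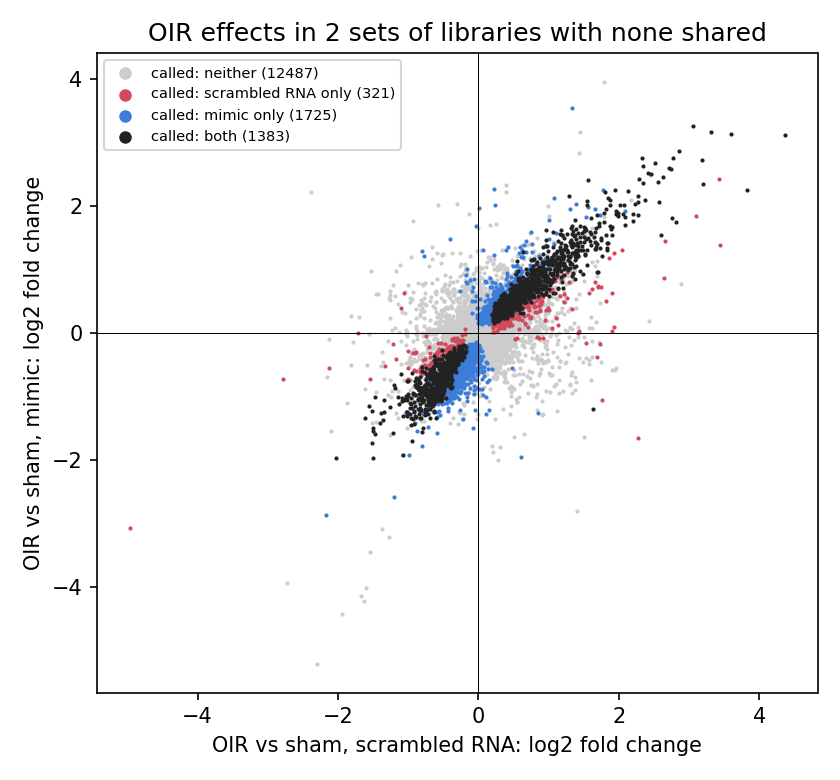
Log2 fold change of OIR against sham with scrambled RNA (horizontal axis) and with the mimic (vertical axis), 1 point per tested gene. The 1383 genes called in both comparisons (black) lie along the diagonal, apart from the 1 with opposite signs.

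Averaged over both injections, 4813 genes differed between OIR and sham, 2783 higher and 2030 lower (limma, adjusted p below 0.05). The share of higher genes was 57.8%, and 45.7% after quantile normalisation. Beyond 2-fold, 341 of the called genes were higher and 83 lower. Above 1000 TPM 18 genes were called higher and 17 lower, and between 100 and 1000 TPM 386 and 339. Some of the most abundant genes fell. The most abundant gene in sham fell from 43058 ± 1662 TPM to 32142 ± 4880 TPM in OIR (SD, n = 6 each), and each OIR library lay below each sham library (exact permutation test, two-sided, p = 0.00216, the smallest that 6 against 6 can give; adjusted p = 0.00433 over 4 measures). In the limma fit its log2 fold change was -0.51 (SE 0.13, adjusted p 0.0352) with scrambled RNA and -0.37 (SE 0.13, adjusted p 0.0811) with the mimic, where it was not called. The call with scrambled RNA was lost in 11 of 26 other settings. These include leaving out any sham scrambled library (adjusted p 0.0848 to 0.0962), sham mimic replicate 2 or 3 (0.0513 and 0.0523) or OIR scrambled replicate 3 (0.0694), and median-ratio scaling (0.059). Over the 26 settings the log2 fold change of this gene lay between -0.597 and -0.333. It was -0.333 without OIR scrambled replicate 3. The third most abundant gene in sham fell from 13289 ± 790 to 5928 ± 1401 TPM (SD, n = 6 each; exact permutation p = 0.00216). This gene was singled out after its values were seen. In the limma fit its log2 fold change was -1.35 (SE 0.21, adjusted p 0.00393) with scrambled RNA and -1.06 (SE 0.21, adjusted p 0.006) with the mimic. Together, the 10 most abundant genes of the sham libraries took 12.5 ± 0.474% of the TPM in sham and 10.04 ± 1.58% in OIR (SD, n = 6 each; exact permutation p = 0.00866, adjusted p = 0.0115). The same 10 genes are the most abundant over all 12 libraries, and picking 10 genes anew in each division gave the same p. Of these 10 genes, 3 were called lower in the averaged comparison and 0 higher (limma), with 3 called lower with scrambled RNA and 1 with the mimic. With the mimic 4 of the 10 had a positive log2 fold change. The exact tests of 6 against 6 take the 2 sham libraries with the shared number as separate. Within one injection the smallest possible exact p is 0.1. For the share of the 10 genes it was 0.1 with scrambled RNA and 0.2 with the mimic, where OIR mimic replicate 2 (12.31%) lay within the sham range.

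**Figure D3:**
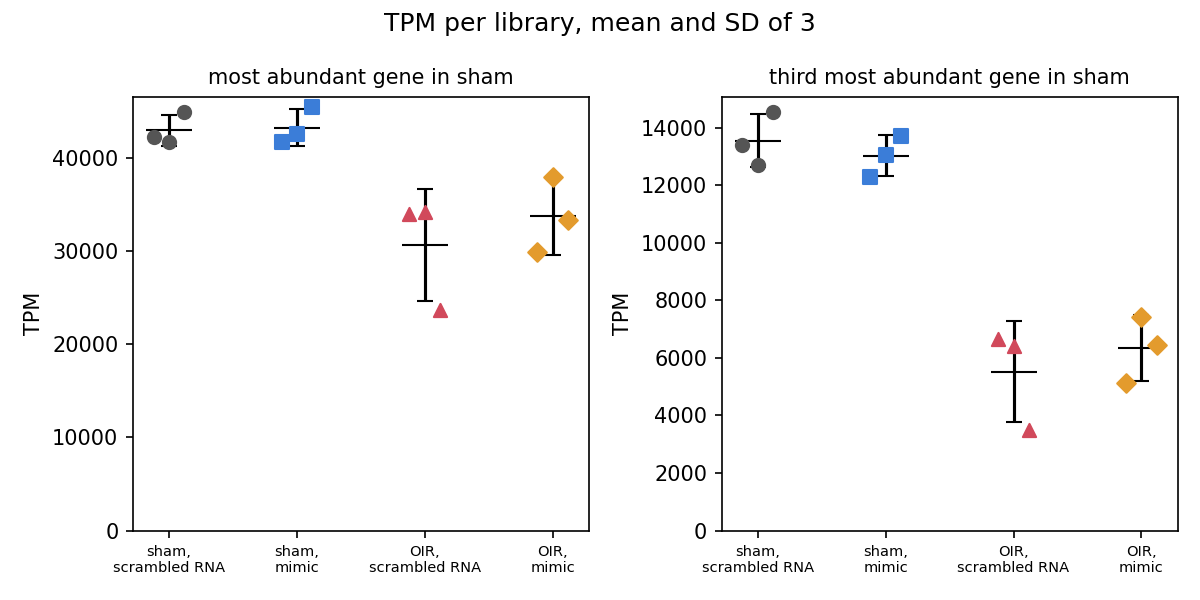
TPM of the most abundant (left) and the third most abundant gene of the sham libraries (right), 1 point per library, with horizontal lines for the mean and bars for the SD of 3 libraries; both vertical axes start at 0. OIR libraries lie at 23696 to 37956 TPM on the left and 3493 to 7416 TPM on the right, below each sham library.

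The effect of the mimic in OIR retinas was tested next. In both mimic comparisons the column names carry the letter L for each mimic library and R for each scrambled library, so that letter and injection go together. No gene differed between mimic and scrambled RNA (limma, 0 of 15916 genes, smallest adjusted p 0.199). At an unadjusted p below 0.05 there were 1491 genes, where 795.8 would be expected by chance, and limma voom on the recovered reads called 0 genes. That number was 759 without OIR mimic replicate 2 and 2363 without OIR mimic replicate 1, so the excess depends on single libraries. For 88.6% of the tested genes the unadjusted 95% interval excluded a 2-fold change in either direction on the log2(TPM + 1) scale. That scale understates the change of low genes, and 5614 of the 15916 tested genes had a mean below 10 TPM. The share therefore does not hold for a 2-fold change in TPM. In simulated data of the same size, 67.8% of 2-fold and 43.6% of 1.5-fold changes were called in this comparison. Without OIR mimic replicate 1, 25 genes were called, 2 higher and 23 lower with the mimic, and without both libraries lacking condition tags 28 were called, 1 higher and 27 lower.

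In sham retinas the mimic likewise gave no call (limma, 0 genes, smallest adjusted p 0.252), with 333 genes at an unadjusted p below 0.05 and 0 genes by limma voom on recovered reads. By chance 795.8 genes would be expected at that unadjusted p, so the test may be conservative there, for a reason that was not tested. Without sham scrambled replicate 3 there were 803 genes at that unadjusted p, without sham mimic replicate 1 757, and with arrayWeights 3226. On the log2(TPM + 1) scale the unadjusted 95% interval excluded a 2-fold change for 89.8% of the genes, with the same limit for low genes. The interaction, which tests whether the mimic effect differed between OIR and sham, gave 0 genes (limma, smallest adjusted p 0.28). It gave 589 at an unadjusted p below 0.05, also below the 795.8 expected by chance, and 0 calls by limma voom. Without OIR mimic replicate 1 the 589 became 1148, and with arrayWeights 1862. Its median standard error was 0.19 on the log2 scale, against 0.13 for a comparison of 2 groups. Across genes, the mimic effects in OIR and in sham had a Pearson r of 0.0752 (jackknife SE 0.0975), a Spearman rho of 0.20 and a covariance of 0.00464 (jackknife SE 0.0073). The Pearson r was 0.010 without OIR mimic replicate 2 and 0.149 with a filter of 5 TPM. Both mimic effects were lower for longer genes (Spearman rho with gene length -0.113 in OIR and -0.208 in sham). Their agreement apart from gene length was not tested.

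The design also allows the question whether genes changed by OIR moved back with the mimic. The log2 fold changes of OIR against sham with scrambled RNA and of mimic against scrambled RNA in OIR had a Pearson r of -0.164 across genes (jackknife SE 0.115) and a Spearman rho of -0.0352. The Pearson r was -0.317 without OIR scrambled replicate 1, -0.318 without OIR scrambled replicate 2 and -0.0924 without OIR mimic replicate 3. Both use the OIR scrambled libraries, and simulated libraries with no effect gave a mean r of -0.497. The simulated noise of each gene had its spread over all 4 groups, not that of the OIR scrambled libraries alone. A larger spread in those 3 would make the simulated covariance more negative. The covariance was -0.0186 (jackknife SE 0.0173), against -0.0283 in the simulation, a difference of 0.00966 that is smaller than the standard error. These values show neither a movement back nor its absence. The 3 shared libraries are too few to be split into parts of at least 2. In the main fit, sharing them is enough for the whole of the negative correlation, since the simulated values are the more negative ones. The covariance was -0.0433 without OIR scrambled replicate 1, -0.0436 without OIR scrambled replicate 2 and -0.0963 with a pseudocount of 0.1. No simulated value was computed for those settings. With an OIR scrambled library left out, fewer libraries are shared. That makes the covariance and the correlation expected without effects more negative. The values without those libraries are therefore no sign of a movement back by themselves.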

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

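The 4 alternatives named in the methods as chosen after seeing the data are marked "added" here. Settings that need gene names (lists, seed sites, the rescaling without named gene classes) were not run. Over the 6 counts of called genes, 134 of 160 values were equal to the reported count or within 1.5 times of it. For the mimic comparisons and the interaction the reported count is 0, so there a ratio measures no stability. For OIR with scrambled RNA, 4 of 12 fits without 1 library and 3 of 15 other settings moved further. With the mimic, 1 of 12 and 1 of 15 did. The averaged OIR comparison stayed within 1.5 times under each alternative run (3985 to 6536 genes). For OIR against sham with scrambled RNA, arrayWeights gave 3322 genes, leaving out both untagged libraries 926 and leaving out both libraries with the shared number (added) 742; with 1 library left out the range was 805 to 2181. With the mimic, arrayWeights gave 5270 and 1 library left out 2041 to 3275. The mimic in OIR gave 1 gene with a pseudocount of 0.1, no filter, no trend and robust options, arrayWeights or only the 2 groups, and 28 without the untagged libraries; the range with 1 library left out was 0 to 25. The mimic in sham gave 2 genes with a pseudocount of 0.1, 1 with 0.5 and 1 with arrayWeights, with 0 to 1 on leaving out a library. The interaction gave 2 genes with a pseudocount of 0.1, 1 with no filter and 1 without trend and robust options, with 0 to 1 on leaving out a library. The cause was not tested, beyond fewer libraries in the fits that leave some out.

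The correlation of OIR and mimic effects was -0.311 with a pseudocount of 0.1 and -0.0311 with a filter of 5 TPM, and -0.318 to -0.0924 with 1 library left out. The correlation of the OIR effects of the scrambled and the mimic groups was 0.515 and 0.65 with pseudocounts of 0.1 and 0.5, 0.647 without a filter, 0.796 with a filter of 5 TPM, 0.599 without the untagged libraries and 0.645 to 0.701 with 1 library left out. No Pearson correlation changed sign with the other pseudocounts and filters, median-ratio scaling, quantile normalisation, 1 library left out or the untagged libraries left out. The correlations were not computed under the other settings. In OIR with scrambled RNA no gene given by identifier or abundance rank changed sign in any setting that gave a value. Their fold changes in other comparisons were not followed across settings. Quantile normalisation gives no value for the most abundant gene, which it sets equal in the compared libraries by construction. In OIR with scrambled RNA the limma call of that gene was lost in 11 of the other 26 settings. With the replicate number as a block the counts were 1799, 3300 and 5026 for OIR with scrambled RNA, with the mimic and averaged, and 0 for the mimic comparisons and the interaction. Deviations of same-numbered libraries correlated above 0.1 in 5 of 18 pairs (-0.0481 to 0.258), so the replicate numbers were not taken to pair libraries; the highest value was that of the pair with a shared column number, whose relation stays open. Low genes rest on few reads, as does the gene called on 10 reads, and the effect of depth was not tested.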

Other observations

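The tests in this part were chosen, or their predictions written, after the results were seen. A group of 19 genes had an on/off pattern, with a gap of over 2 log2 units between libraries, at least 30 reads in each library in the on state, and 2 to 10 libraries on. The gap also had to make up most of the gene's log2 range over all libraries. On and off name the levels above and below the gap. Off does not mean absent, as 1 gene stood at 7.07 to 11.7 TPM in its off state. Of these, 4 divided the 6 OIR libraries from the 6 sham libraries completely. The gene ENSRNOG00000005826 is another of the 19, off in each OIR library and in 1 of 6 sham libraries.

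A further 7 of the 19 formed a block with 1 pattern. In it, 5 genes were on in 7 libraries and the other two were on in exactly the remaining 5 libraries. The on state of the 5 genes was found in 5 of 6 OIR and 2 of 6 sham libraries (Fisher's exact test, two-sided, p = 0.242). With the state of the block as a covariate, 81.2% of the genes called for OIR with scrambled RNA stayed called, and the count was 1567, so the imbalance does not account for most of these calls. With the mimic 68.2% stayed called (count 2385, of which 43.1% higher), and averaged over both injections 74.8% (count 3995). There a part played by the block cannot be told apart from OIR, because with the mimic 3 of 3 OIR libraries and 1 of 3 sham libraries were on. The sex of the animals is a candidate explanation for the block of 7 genes, but it cannot be told apart from others because the labels give no sex and the identifiers no names.

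More genes were higher than lower in OIR with scrambled RNA (63.4%), and beyond 2-fold the share was 86.6%. The 10 most abundant genes of the sham libraries took 12.40% of the TPM in sham and 9.43% in OIR with scrambled RNA. Scaling to a fixed total raises all other genes when such genes lose share. With libraries scaled to the total of the other genes, 51.0% of 1829 called genes were higher (59.0% without OIR scrambled replicate 3, and 46.1% without OIR mimic replicate 2). This scaling brought the median log2 fold change from 0.0465 to 0.00202. Median-ratio scaling, which does not set these 10 genes apart, brought the median to 0.00621 with 49.9% of the called genes higher. A median near 0 did not always even out the calls, as it was 0.00563 in the fit with 59.0%. The lost share of the 10 most abundant genes therefore cannot be told apart from other common shifts as a source of the excess over all called genes. It does not account for the excess beyond 2-fold, where the share was 83.5% and at least 78.8% with 1 library left out. The shift in the median is small beside a 2-fold change, so the rescaling could hardly have moved this share. Gene length stays open as a part of the excess over all called genes. Among the longer genes 55.8% of the called genes were higher, against 72.3% among the shorter genes, and the lowest share for the longer genes with 1 library left out was 49.1%. An effect of OIR itself on the balance was not tested separately.

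Sham scrambled replicate 1 and sham mimic replicate 1, the libraries with the shared number, had the same state in 3 of the 8 on/off genes outside the block and outside the OIR division. The other 65 pairs of libraries shared 0 to 7, and 59 of them agreed in at least as many genes. In the block the libraries with the shared number agreed in each of the 7 genes, as did 30 of the other 65 pairs, and they are the 2 sham libraries with the on state. The correlation of their deviations from the group means was 0.258, and the highest of the other 53 pairs between groups was 0.20. Whether these libraries are related stays open, since the labels do not explain the number.

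Other divisions of the libraries were fitted in the same way. For OIR against sham averaged over both injections, 1 of 100 divisions, the real one, gave as many as 4813 genes, and the highest of the others gave 4. That makes a chance division of the libraries unlikely. It does not exclude it, since 1 of 100 is the smallest share that 100 divisions can give. The test also takes the 2 sham libraries with the shared number as separate. Without both of them the real division gave 4035 genes, and other divisions were not fitted there. The 10 divisions of 3 against 3 are too few for a share under 0.05. There the real count was 1704 and the highest other 2 for OIR with scrambled RNA, 3108 and 1 for OIR with the mimic, 0 and 3 for the mimic in OIR, and 0 and 6 for the mimic in sham. With a real count of 0, as in both mimic comparisons (10 of 10 divisions) and the interaction (100 of 100), each division gives at least as many by construction, so the test says nothing there. In the interaction division with the highest count, 1118 genes were called, against 4 in the next, which points to a structure among the libraries that the groups do not follow. It set sham scrambled replicates 1 and 2, sham mimic replicate 1, OIR scrambled replicates 1 and 3 and OIR mimic replicate 1 against the rest. The former are the libraries with positive values on the second principal component.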
